A study of Arabidopsis thaliana with 36 samples.

How the data were processed

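Samples were leaves of 4-week-old Arabidopsis thaliana plants of wild type Col-0, Atelp2 and npr1, taken at 0, 4, 8 and 12 h after pressure infiltration with Pseudomonas syringae pv. tomato DC3000 carrying avrRpt2. Each sample pooled leaves of 8 plants, with 3 biological replicates per group, and 200 ng of total RNA was labelled with Cy3 per the labels. Groups follow the titles and characteristics. For 3 npr1 samples the source name gives 24 h where every other label gives 12 h, and they were grouped as 12 h. The alleles and the authors' statistical method are not given in the sources used here.

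The deposited scanner files hold intensity values, background-subtracted and detrended within the array by Agilent Feature Extraction 10.1.1.1 per the file headers, for 43803 non-control spots of 43603 probes. Per the file headers they also give flags of other kinds for each spot (well above background, saturated, outlier). The deposited series table holds values of 33143 of these probes, taken here as log2 values that the authors scaled between arrays as deposited. Neither the unit nor the method is given in the sources used here. All of its columns share a median of 8.487 and an interquartile range of 8.155, which is why it was taken as scaled. Its columns correlate with log2 signal of their own array at r = 0.968 to 0.973. They rise by 0.881 to 1.05 per log2 unit of that signal, where log2 values in proportion to it would rise by 1.

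Of the probes, 37540 name 1 locus, 873 several and 5190 none. The files name an older genome build (ath1) than the reference table used for symbols and neighbours, in which 28074 of 28479 loci were found. Only probes of 1 locus were tested as genes.

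Signal was analysed as log2 of the processed signal minus each array's 75th percentile. Repeated spots of a probe were averaged without those flagged as outliers, and each gene was read from its probe with the highest mean over all arrays. Probes were kept if well above background on all 3 arrays of at least 1 group, which left 21328 genes. Per array 66.0% to 75.7% of spots were well above background (median 71.7%), and the 75th percentile of signal ran from 1622 to 6829. Between 13 and 97 spots per array were saturated.

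limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 36 arrays (lmFit, contrasts.fit, eBayes), with no block. The comparisons were each genotype at 4, 8 and 12 h against its 0 h, each mutant against wild type at each time, the difference of these changes between each mutant and wild type, and Atelp2 against npr1. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The comparisons, the 22 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined.

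The gene lists hold 331 members, of which 326 were tested: salicylic acid synthesis and signalling, pathogenesis-related and systemic resistance genes, endoplasmic reticulum folding and secretion, jasmonate synthesis and JAZ genes, jasmonate and ethylene defence outputs, tryptophan with camalexin and indole glucosinolates, pattern-triggered signalling, intracellular immune receptors, photosynthesis, circadian clock, Elongator subunits, anthocyanin and flavonoid synthesis, oxidative stress, cell division, guard cell, vascular and epidermis markers, leaf senescence, heat shock, abscisic acid, auxin response and reference genes. They were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists and comparisons of a family, and again with a correlation estimated from the residuals. Neither the preset nor the estimate can be taken as exact. In comparisons simulated from the residuals of the arrays, the preset gave p under 0.05 in 30.8% of 594 list tests without any true change and the estimate in 3.70%. After adjustment over all 594 the preset still called 124 and the estimate 0. A call at the preset alone therefore does not establish a shift of a list.

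Genes named are the 5 highest and 5 lowest called genes of a comparison whose groups of arrays do not overlap, up to 4 called members of each list with the largest change, every member of lists of fewer than 8 genes, and always ELP2, NPR1, ICS1, PAD4, EDS1, PR1, PR2, PR5, PDF1.2A and ORA59. The text names some of these. The fit was tested on simulated data with 200 changed genes among 21193. For Atelp2 against wild type at 8 h it recovered 41.8%, 67.2% and 90.9% of changes of 1.5-, 2- and 4-fold. For the difference of changes at 8 h it recovered 23.9%, 61.2% and 75.8%. Of the genes called, 6.99% and 2.73% were unchanged ones in these 2, 9.93% for npr1 against wild type at 0 h and 7.79% for wild type at 4 h against 0 h, so in 3 of the 4 simulated comparisons the false share lay above the nominal 5%.

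The arrays lie on 9 slides of 4, in 3 layouts. The slides of wild type 0 h, npr1 0 h, Atelp2 0 h and wild type 4 h hold no other group, nor do those of npr1 4 h, Atelp2 4 h, wild type 8 h and npr1 8 h, or those of the rest. At 4 h both mutants thus lay on other slides than wild type, and at 8 h Atelp2 lay on other slides than wild type and npr1. A difference between slides cannot be told apart from genotype in these comparisons. Replicate 1 of every group (12 arrays) was scanned in session 1 and replicates 2 and 3 (24 arrays) in session 2. Alternatives changed 1 choice at a time: quantile normalization, normexp background correction with an offset of 50 on raw signal and background, no filter, the mean of a gene's probes, a replicate block, the scan session as a block, the slide as a block (fixed in 9 comparisons, random in 18), only the groups compared, the authors' processed values, and leaving out each array in turn. Session 2 alone, and the gene lists with a session block, were added after the data were seen. Reading and drawing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Probes of several loci or none were left out of the gene tests.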

Results

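Leaf transcripts of Arabidopsis thaliana were measured on 36 one-colour arrays from plants infiltrated with Pseudomonas syringae carrying avrRpt2. Wild type Col-0, Atelp2 (a mutant of Elongator subunit 2) and npr1 were sampled at 0, 4, 8 and 12 h, with 3 biological replicates in each of 12 groups. There was no mock-infiltrated arm, so a change from 0 h mixes the bacteria, the infiltration and the time of day. Except for wild type at 4 h, the later arrays also lay on other slides than the 0 h arrays. A difference between slides is mixed in there too. Of 28479 loci, 21328 had a probe well above background on all 3 arrays of at least 1 group and were tested with limma. Replicates of a group correlated at r = 0.978 to 0.994. Values below are log2 fold changes with limma's standard error, with n = 3 arrays per group. This error rests on 1 variance per gene over all 36 arrays. It is too small where the groups compared vary more than the rest. Genes were called at an adjusted p under 0.05, and every change described as a rise or a fall met that limit.

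Component 1 of the arrays' variance (66.0%) ran from 0 h to the later times, and component 2 (9.31%) set 4 h apart. At 8 h the Atelp2 arrays lay between the 4 h and the 12 h arrays of wild type.

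**Figure D1:**
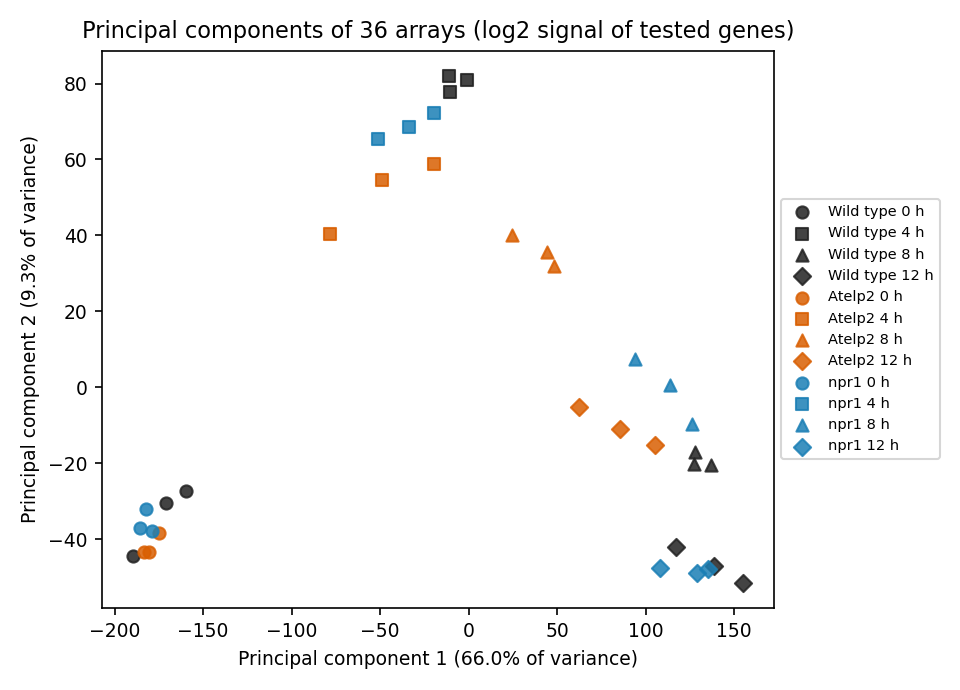
Position of the 36 arrays on the first 2 principal components of log2 signal, coloured by genotype and shaped by hour. Each point is 1 array, and component 1 holds 66.0% of the variance.

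The 2 mutated genes gave less signal in their own mutants at every time. ELP2, which encodes Elongator subunit 2, was lower in Atelp2 (−0.98, −1.1, −2.13 and −1.53) at 0, 4, 8 and 12 h (SE 0.11 each, adjusted p = 1.2e-07 at 0 h). NPR1, the salicylic acid receptor and coactivator, was lower in npr1 (−1.39, −1.92, −2.09 and −2.02) at the same times (SE 0.10 each, adjusted p = 3.4e-10 at 0 h). The labels name no allele, so whether either probe lies in the altered part of its gene is unknown. NPR1 was also lower in Atelp2, at −0.45 ± 0.10, −1.79 ± 0.10 and −0.45 ± 0.10 at 0, 4 and 8 h, and its value at 12 h was 0.03 ± 0.10, adjusted p = 0.86. Of the 6 Elongator subunit genes, 1 was higher in Atelp2 at 0 h and 1, ELP2 itself, was lower (2 adjusted over the list alone, camera adjusted p = 0.85, adjusted p = 0.93 with an estimated correlation).

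By 4 h after inoculation transcripts of salicylic acid synthesis and immune signalling had risen in wild-type leaves. ICS1, whose enzyme makes the precursor isochorismate, rose by 5.68 ± 0.25, and EDS5, its transporter, by 6.84 ± 0.27. PBS3, which conjugates isochorismate to glutamate, rose by 6.54 ± 0.38, and the immune regulators PAD4 and EDS1 by 5.51 ± 0.29 and 4.13 ± 0.20. The calmodulin-like gene CML37 rose by 9.40 ± 0.50, the camalexin gene PAD3 by 8.71 ± 0.60 and the kinase gene MPK11 by 7.63 ± 0.41. In all, 12990 genes were called, 4951 higher and 8039 lower. Among the falls were the gibberellin-regulated peptide gene GASA6 (−4.45 ± 0.42), the BTB and TAZ domain gene BT2 (−4.74 ± 0.22) and the auxin-response gene IAA6 (−3.62 ± 0.22). PR1, a marker of salicylic acid output, was not called, at −2.0 ± 1.09, adjusted p = 0.12, and was above background on 2 of 3 arrays at both times.

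Of 23 genes of salicylic acid synthesis and signalling, 21 rose and 1 fell at 4 h in wild type (22 adjusted over the list alone, camera adjusted p = 9.7e-13, adjusted p = 0.13 with an estimated correlation). Pattern-triggered signalling rose in 18 of 19 genes, with FRK1 up by 6.04 ± 0.59 (18 adjusted over the list alone, camera adjusted p = 1.6e-13, adjusted p = 0.13 with an estimated correlation). The tryptophan, camalexin and indole glucosinolate list rose in 15 of 16, CYP81F2 by 6.47 ± 0.28 (15 adjusted over the list alone, camera adjusted p = 3.2e-08, adjusted p = 0.13 with an estimated correlation). For intracellular immune receptors and their partners it was 14 of 16, SGT1A by 4.36 ± 0.18 (14 adjusted over the list alone, camera adjusted p = 3.1e-08, adjusted p = 0.13 with an estimated correlation). Heat shock genes rose in 9 of 12, with HSFA2, a heat shock factor, up by 8.19 ± 0.24 (10 adjusted over the list alone, camera adjusted p = 2.7e-07, adjusted p = 0.086 with an estimated correlation). Jasmonate synthesis and JAZ genes went both ways, 13 higher and 3 lower: AOC3, an allene oxide cyclase, by 4.72 ± 0.27, and JAZ7, a repressor (−3.33 ± 0.22; 16 adjusted over the list alone, camera adjusted p = 0.0036, adjusted p = 0.36 with an estimated correlation). Cell division genes fell in 14 of 15, among them MCM2 and PCNA1 of DNA replication (−2.40 ± 0.19 and −2.03 ± 0.22; 14 adjusted over the list alone, camera adjusted p = 2.1e-04, adjusted p = 0.28 with an estimated correlation).

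At 8 h in wild type PR1 and genes of the secretory machinery stood above 0 h. PR1 rose by 8.03 ± 1.09 against 0 h, where it was above background on 2 of 3 arrays, and NIMIN2, which encodes an NPR1-binding protein, by 7.22 ± 0.41. The chaperone gene BIP2 of the endoplasmic reticulum rose by 4.47 ± 0.14 and the disulfide isomerase gene PDIL2-2 by 4.87 ± 0.15. Chloroplast genes fell: LHCB2.1 of the light-harvesting complex (−4.55 ± 0.31), and PORB and HEMA1 of chlorophyll synthesis (−4.01 ± 0.26 and −4.0 ± 0.14). GASA6 fell further (−8.44 ± 0.42). The calls numbered 16758, 7808 higher and 8950 lower.

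Endoplasmic reticulum folding and secretion rose in 17 of 17 genes at 8 h (17 adjusted over the list alone, camera adjusted p = 1.2e-08, adjusted p = 0.13 with an estimated correlation). Photosynthesis genes of the mesophyll fell in 37 of 41 (37 adjusted over the list alone, camera adjusted p = 2.5e-06, adjusted p = 0.38 with an estimated correlation). The epidermis and trichome markers fell in 5 of 6 (5 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.32 with an estimated correlation). The Elongator subunit genes rose in 6 of 6, ELP4 by 2.21 ± 0.09 (6 adjusted over the list alone, camera adjusted p = 0.0086, adjusted p = 0.26 with an estimated correlation).

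At 12 h in wild type, 16373 genes differed from 0 h, 7619 higher and 8754 lower. PR1 stood 8.97 ± 1.09 above 0 h, and PR2, a glucanase gene, 3.90 ± 0.78. SAG13, a senescence marker, rose by 7.44 ± 0.82, and ORE1, a transcription factor of senescence, by 6.11 ± 0.47. LHCB2.1 fell (−7.86 ± 0.31), and the cytokinesis gene KNOLLE (−3.58 ± 0.23). All 41 photosynthesis genes fell (41 adjusted over the list alone, camera adjusted p = 8.5e-10, adjusted p = 0.29 with an estimated correlation). The 7 leaf senescence genes all rose (7 adjusted over the list alone, camera adjusted p = 0.0016, adjusted p = 0.23 with an estimated correlation), while of the pathogenesis-related and systemic resistance genes 8 of 9 rose (9 adjusted over the list alone, camera adjusted p = 0.0036, adjusted p = 0.27 with an estimated correlation). Auxin response fell in 12 of 15 (15 adjusted over the list alone, camera adjusted p = 0.010, adjusted p = 0.23 with an estimated correlation). Oxidative stress and detoxification rose in 14 and fell in 5 of 19 (19 adjusted over the list alone, camera adjusted p = 0.0014, adjusted p = 0.23 with an estimated correlation). Guard cell markers fell in 4 of 6 (5 adjusted over the list alone, camera adjusted p = 0.24, adjusted p = 0.37 with an estimated correlation). The circadian clock list had 4 higher and 8 lower of 16 (12 adjusted over the list alone, camera adjusted p = 0.30, adjusted p = 0.34 with an estimated correlation). The 11 reference genes had 3 higher and 1 lower, with a median of 0.08 (4 adjusted over the list alone, camera adjusted p = 0.54, adjusted p = 0.67 with an estimated correlation).

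Each wild-type comparison with 0 h was tested with limma. With the scan session as a block, 14835, 17923 and 17616 genes were called at 4, 8 and 12 h. The median of all tested genes lay at −0.20, −0.14 and −0.12, and normexp background correction moved it to −0.37, −0.53 and −0.46.

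**Figure D2:**
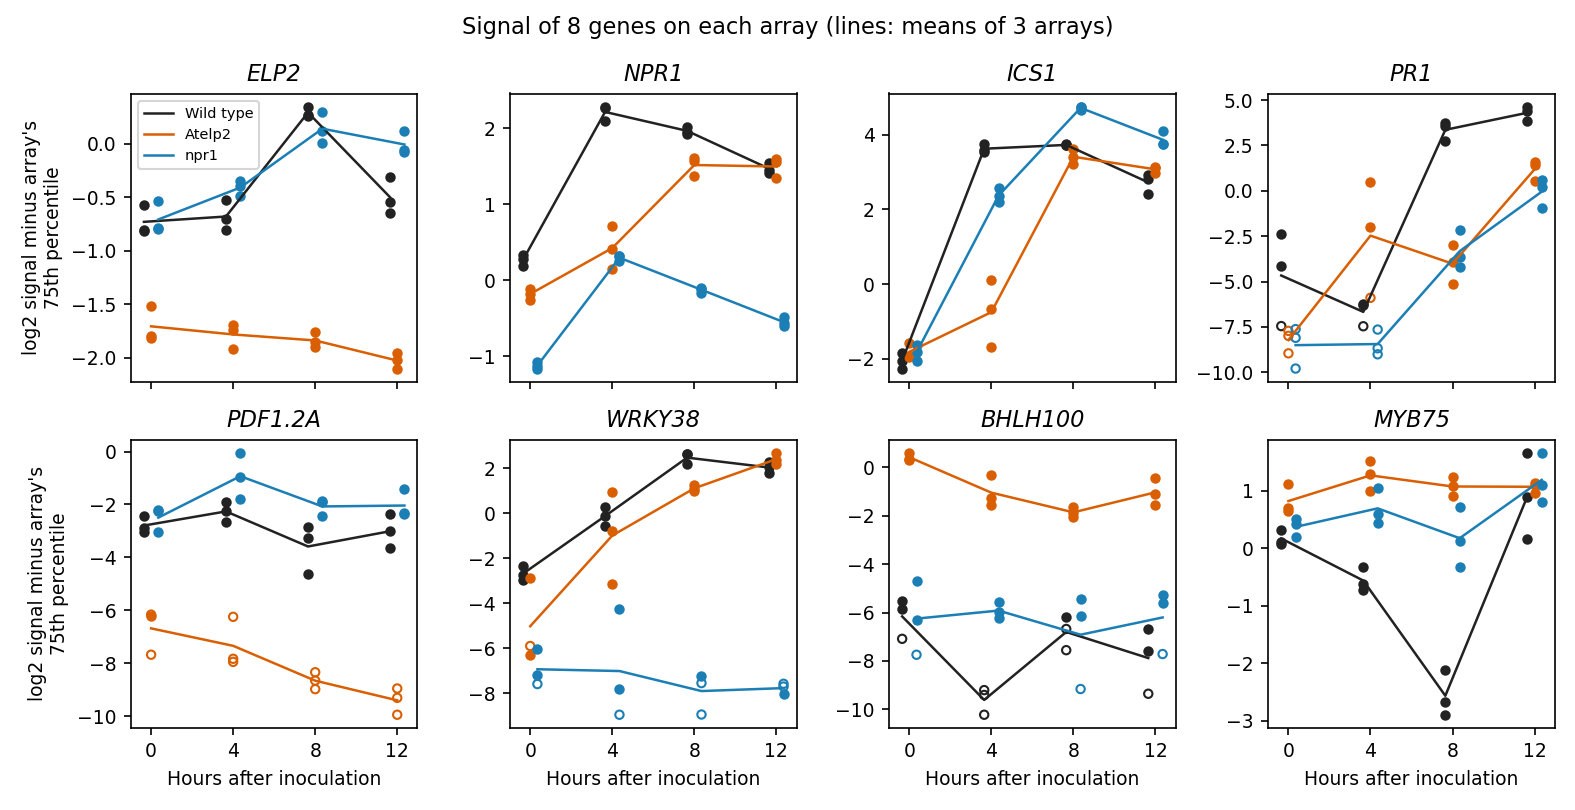
Signal of 8 genes (log2, minus the array's 75th percentile) against hours after inoculation in the 3 genotypes, where filled points are arrays well above background, open points are the rest, and lines join means of 3 arrays. ICS1 at 4 h in Atelp2 lay −4.38 log2 units from wild type.

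In Atelp2 the same 3 time points gave 12834, 14690 and 15536 genes against its own 0 h, 5221, 5711 and 6670 of them higher. ICS1 rose by 1.06 ± 0.25 at 4 h and 5.22 ± 0.25 at 8 h, and PAD4 by 2.1 ± 0.29 and 5.55 ± 0.29. BIP2 rose by 2.66 ± 0.14 at 8 h and 3.24 ± 0.14 at 12 h. The salicylic acid list rose in 20 of 23 genes at 4 h (21 adjusted over the list alone, camera adjusted p = 1.0e-08, adjusted p = 0.20 with an estimated correlation). All 22 genes of jasmonate synthesis and JAZ rose at 8 h (22 adjusted over the list alone, camera adjusted p = 3.7e-09, adjusted p = 0.15 with an estimated correlation). Anthocyanin and flavonoid genes rose in 10 of 15 at 12 h (11 adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.34 with an estimated correlation). All 41 photosynthesis genes fell by then (41 adjusted over the list alone, camera adjusted p = 3.8e-08, adjusted p = 0.33 with an estimated correlation). Abscisic acid and water stress genes rose in 13 of 15 at 4 h (13 adjusted over the list alone, camera adjusted p = 1.7e-07, adjusted p = 0.086 with an estimated correlation).

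In npr1, 12277, 16455 and 16451 genes differed from 0 h, 5031, 7427 and 7592 of them higher. ICS1 rose by 4.2 ± 0.25 at 4 h and 6.55 ± 0.25 at 8 h, and EDS1 by 3.15 ± 0.20 at 4 h. All 16 genes of the tryptophan, camalexin and indole glucosinolate list rose at 4 h (16 adjusted over the list alone, camera adjusted p = 3.2e-08, adjusted p = 0.13 with an estimated correlation). All 41 photosynthesis genes fell at 12 h (41 adjusted over the list alone, camera adjusted p = 1.1e-09, adjusted p = 0.29 with an estimated correlation). Salicylic acid genes rose in 17 of 23 at 12 h (20 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.27 with an estimated correlation).

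Both mutants' courses were tested with limma. With the scan session as a block the calls were 14725, 16235 and 17033 in Atelp2 and 14269, 17641 and 17744 in npr1. The median of all tested genes lay between −0.23 (Atelp2 at 8 h) and −0.12 (npr1 at 12 h), and normexp moved the value of Atelp2 at 8 h to −0.34. The ICS1 call of Atelp2 at 4 h ended when only the groups compared were fitted; its 3 arrays read −0.67, 0.11 and −1.69 (log2 minus the 75th percentile).

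**Figure D3:**
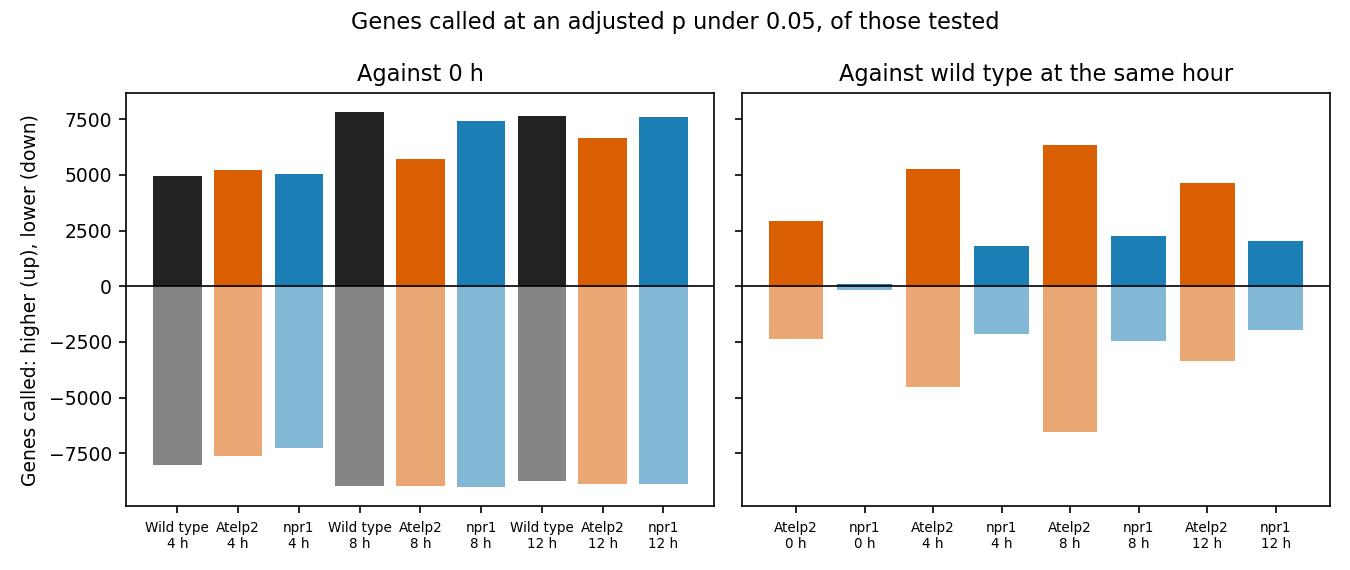
Number of genes called at an adjusted p under 0.05, higher (upward bars) and lower (downward bars), against 0 h (left) and against wild type at the same hour (right), from 3 arrays per group. Atelp2 differed from wild type in 12882 genes at 8 h and npr1 in 4755.

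At 0 h Atelp2 leaves had lower defence transcripts and higher iron regulators than wild type. WRKY54 and WRKY70, transcription factors of the salicylic acid branch, were lower (−2.11 ± 0.34 and −1.92 ± 0.32), and RPS2, the receptor that senses the action of AvrRpt2 (−1.56 ± 0.21). PR2 was lower (−2.27 ± 0.78) and PR5, a thaumatin-like protein gene (−1.37 ± 0.39). The iron-regulator gene bHLH38 was higher by 4.77 ± 0.64, AGL19, a MADS-box gene of flowering, by 5.45 ± 0.22, and CML41 by 5.18 ± 0.40. PHI-1 was lower (−6.94 ± 0.38), and so was TCH4, a cell wall xyloglucan enzyme gene (−4.51 ± 0.29). In all, 5279 genes were called, 2928 higher and 2351 lower.

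At 0 h the salicylic acid list was lower in Atelp2 in 9 of 23 genes (12 adjusted over the list alone, camera adjusted p = 5.6e-05, adjusted p = 0.53 with an estimated correlation). Jasmonate and ethylene defence outputs were lower in 7 of 11, with ACS6, an ethylene synthesis gene, at −2.39 ± 0.24 (8 adjusted over the list alone, camera adjusted p = 8.4e-04, adjusted p = 0.33 with an estimated correlation). PDF1.2A, a defensin gene, was lower (−3.89 ± 0.50), above background on 1 of 3 Atelp2 arrays. Immune receptors were lower in 8 of 16 (13 adjusted over the list alone, camera adjusted p = 0.0079, adjusted p = 0.56 with an estimated correlation) and pattern-triggered signalling in 8 of 19 (12 adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.56 with an estimated correlation). Vascular markers were lower in 3 of 9 (5 adjusted over the list alone, camera adjusted p = 0.020, adjusted p = 0.39 with an estimated correlation). The anthocyanin list was higher in 4 of 15, CHS by 1.90 ± 0.40 (4 adjusted over the list alone, camera adjusted p = 0.020, adjusted p = 0.56 with an estimated correlation).

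At 4 h genes of salicylic acid synthesis were lower in Atelp2 than in wild type. ICS1 was lower (−4.38 ± 0.25), PBS3 (−4.05 ± 0.38), EDS5 (−3.85 ± 0.27) and CBP60G, a transcription factor gene upstream of ICS1 (−3.84 ± 0.25). PAD4 and EDS1 were lower (−3.67 ± 0.29 and −3.0 ± 0.20), PAD3 (−5.46 ± 0.60), and the MAP kinase cascade genes MKK4 and MPK3 (−3.62 ± 0.17 and −3.26 ± 0.22). JAZ7 and JAZ8 were higher by 3.05 ± 0.22 and 2.25 ± 0.33, the drought-responsive factor gene RD26 by 2.68 ± 0.19 and the dehydrin gene LTI30 by 2.60 ± 0.20. PDF1.2A was dim on all 3 Atelp2 arrays and at least 19.7-fold lower (adjusted p = 4.1e-09). Such bounds set the mean of the bright group against the mean of the dim one. For each dim array they use the higher of the lowest signal among probes well above background and the probe's own. These bounds leave out the spread between arrays, so they are not confidence limits. PR1 was higher in Atelp2 by 4.2 ± 1.09, above background on 2 of 3 arrays in both groups. Atelp2 arrays at 4 h varied widely for some of these genes. Their SD was 0.90 for ICS1, 0.97 for PAD4, 0.70 for EDS1 and 3.21 for PR1, which the pooled standard errors understate.

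Of the salicylic acid genes 19 of 23 were lower in Atelp2 at 4 h and 1 higher (20 adjusted over the list alone, camera adjusted p = 8.0e-11, adjusted p = 0.30 with an estimated correlation). Pattern-triggered signalling was lower in 16 of 19 (17 adjusted over the list alone, camera adjusted p = 6.0e-09, adjusted p = 0.30 with an estimated correlation). Immune receptors were lower in 14 of 16, SGT1A (−3.12 ± 0.18; 16 adjusted over the list alone, camera adjusted p = 6.5e-09, adjusted p = 0.28 with an estimated correlation), and so was the camalexin list in 13 of 16 (15 adjusted over the list alone, camera adjusted p = 8.5e-04, adjusted p = 0.48 with an estimated correlation). Heat shock genes were lower in 7 of 12, HSFA2 (−4.86 ± 0.24; 9 adjusted over the list alone, camera adjusted p = 0.0022, adjusted p = 0.30 with an estimated correlation). Jasmonate synthesis and JAZ genes were higher in 14 of 22 (15 adjusted over the list alone, camera adjusted p = 9.0e-04, adjusted p = 0.53 with an estimated correlation), as were 10 of 15 abscisic acid and water stress genes (10 adjusted over the list alone, camera adjusted p = 7.0e-05, adjusted p = 0.18 with an estimated correlation). Jasmonate and ethylene defence outputs moved the other way, 8 of 11 lower, ERF1 (−3.67 ± 0.30; 9 adjusted over the list alone, camera adjusted p = 3.1e-04, adjusted p = 0.30 with an estimated correlation). Vascular markers were lower in 5 of 9 (5 adjusted over the list alone, camera adjusted p = 0.010, adjusted p = 0.33 with an estimated correlation).

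By 8 h ICS1 and PAD4 stood at −0.32 ± 0.25, adjusted p = 0.28 and −0.48 ± 0.29, adjusted p = 0.15 in Atelp2 against wild type, while output genes differed. PR1 was lower (−7.38 ± 1.09), XTH10, a xyloglucan enzyme gene (−6.47 ± 0.38), and ORA59, which drives defensin genes (−3.81 ± 0.37). The chaperone genes BIP3 and BIP2 were lower (−3.81 ± 0.50 and −1.85 ± 0.14), and PDIL2-2 (−1.81 ± 0.15). The jasmonate-responsive storage protein genes VSP2 and VSP1 were higher by 4.46 ± 0.42 and 4.31 ± 0.43, and AOC1 of jasmonate synthesis by 3.23 ± 0.24. Anthocyanin genes were higher: CHS by 4.30 ± 0.40, the regulator MYB75 by 3.64 ± 0.28, and DFR, dim on the wild-type arrays, at least 13.1-fold (adjusted p = 3.4e-06). PYK10, a beta-glucosidase gene of endoplasmic reticulum bodies, was at least 94.4-fold higher (adjusted p = 3.1e-10), and PDF1.2A at least 11.8-fold lower (adjusted p = 4.1e-09).

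All 17 genes of endoplasmic reticulum folding and secretion were lower in Atelp2 at 8 h (17 adjusted over the list alone, camera adjusted p = 3.1e-10, adjusted p = 0.18 with an estimated correlation). Photosynthesis genes were higher in 27 of 41, LHCB1.1 by 2.03 ± 0.41 (27 adjusted over the list alone, camera adjusted p = 1.2e-04, adjusted p = 0.69 with an estimated correlation). Jasmonate synthesis and JAZ genes were higher in 17 of 22 (18 adjusted over the list alone, camera adjusted p = 2.2e-05, adjusted p = 0.42 with an estimated correlation). The anthocyanin list was higher in 13 of 15 (14 adjusted over the list alone, camera adjusted p = 3.6e-04, adjusted p = 0.40 with an estimated correlation) and the epidermis and trichome markers in 4 of 6 (4 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.56 with an estimated correlation). Elongator subunit genes were lower in 5 of 6, ELP2 included (6 adjusted over the list alone, camera adjusted p = 0.0030, adjusted p = 0.39 with an estimated correlation).

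At 12 h EDS1 was higher in Atelp2 than in wild type by 1.07 ± 0.20 and PAD4 by 0.99 ± 0.29, and PR1 was lower (−3.12 ± 1.09) and the camalexin gene CYP71A13 (−2.17 ± 0.57). LHCB1.1 and LHCB2.1 were higher by 3.60 ± 0.41 and 2.25 ± 0.31, DFR by 5.54 ± 0.82 and the flavonoid glycosyltransferase gene UF3GT by 6.10 ± 0.68, above background on 2 of 3 wild-type arrays. IAR3 and ILL5, hydrolases of amino acid conjugates, were lower (−4.09 ± 0.25 and −3.94 ± 0.20), OSM34, an osmotin-like gene (−4.67 ± 0.54) and GH3.3, an auxin-conjugating enzyme gene (−3.39 ± 0.30).

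Photosynthesis genes were higher in 30 of 41 in Atelp2 at 12 h (36 adjusted over the list alone, camera adjusted p = 2.4e-09, adjusted p = 0.53 with an estimated correlation). Cell division genes were higher in 11 of 15, CYCB1;2 by 1.69 ± 0.26 (11 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.53 with an estimated correlation), and the anthocyanin list in 12 of 15 (12 adjusted over the list alone, camera adjusted p = 2.4e-09, adjusted p = 0.18 with an estimated correlation). The endoplasmic reticulum list was lower in 13 of 17 (13 adjusted over the list alone, camera adjusted p = 3.6e-06, adjusted p = 0.30 with an estimated correlation) and the camalexin list in 9 of 16 (9 adjusted over the list alone, camera adjusted p = 3.6e-04, adjusted p = 0.44 with an estimated correlation). Jasmonate synthesis and JAZ genes, higher at 8 h, were now lower in 11 and higher in 3 of 22 (15 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.68 with an estimated correlation).

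The limma tests of Atelp2 against wild type called 9788 genes at 4 h (5267 higher, 4521 lower), 12882 at 8 h (6355, 6527) and 8002 at 12 h (4633, 3369). Session 1 holds 1 array per group and allows no test. Across all tested genes its fold changes correlated with those of session 2 at r = 0.80, 0.92, 0.92 and 0.93 at 0, 4, 8 and 12 h. With the scan session as a block limma called 7375, 11829, 14670 and 10314 at 0, 4, 8 and 12 h. The authors' processed values split the calls otherwise, 4043 higher and 6645 lower at 8 h and 2155 and 2958 at 12 h. The median of all genes moved to −0.15 at 0 h with normexp and to −0.11 at 8 h with quantile normalization. The calls of PR2 and NPR1 at 0 h and of PAD4 at 12 h ended with the authors' values, and those of PR1 at 4 h and CYCB1;2 at 12 h with normexp. In session 2 the calls of CHS, NPR1, PR2 and PR5 at 0 h, PR1 at 4 h, and CYP71A13, PAD4 and PR1 at 12 h ended. The PR1 call at 12 h also ended when Atelp2 12 h replicate 1 was left out.

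At 0 h npr1 differed from wild type in 294 genes. MRD1 was higher by 4.41 ± 0.27 and the salicylic acid glucosyltransferase gene UGT74F1 by 1.70 ± 0.23. Both calls ended with only the groups compared. NIMIN2 was lower (−1.74 ± 0.41), ICS2, the second isochorismate synthase gene (−0.72 ± 0.11), and the dehydrin genes COR47 and ERD10 (−0.72 ± 0.16 and −0.70 ± 0.15). PAD3 was dim in npr1 and at least 7.68-fold lower (adjusted p = 3.5e-04), and WRKY38 was lower (−4.24 ± 0.89), above background on 2 of 3 npr1 arrays. PR1, dim on all 3 npr1 arrays and above background on 2 of 3 wild-type arrays, was not called (adjusted p = 0.082). The wild-type arrays had an SD of 2.57, so no minimum fold is given. The salicylic acid list was lower in 4 of 23 (5 adjusted over the list alone, camera adjusted p = 3.6e-04, adjusted p = 0.56 with an estimated correlation). Among abscisic acid and water stress genes, 2 of 15 were lower (4 adjusted over the list alone, camera adjusted p = 3.9e-07, adjusted p = 0.18 with an estimated correlation).

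At 4 h NIMIN2 was lower in npr1 than in wild type (−3.92 ± 0.41), NIMIN1 (−3.21 ± 0.52), WRKY54 (−3.68 ± 0.34) and PCC1, a defence-responsive gene (−4.32 ± 0.53). WRKY59, dim on the npr1 arrays, was at least 19.1-fold lower (adjusted p = 6.0e-10). ICS1, PAD4 and EDS1 were lower (−1.26 ± 0.25, −1.13 ± 0.29 and −1.0 ± 0.20). MRD1 was higher by 6.0 ± 0.27, and PDIL2-2 by 0.96 ± 0.15. Of the salicylic acid genes 19 of 23 were lower (23 adjusted over the list alone, camera adjusted p = 2.2e-14, adjusted p = 0.26 with an estimated correlation). Lower too were 13 of 19 pattern-triggered genes (15 adjusted over the list alone, camera adjusted p = 2.4e-09, adjusted p = 0.30 with an estimated correlation) and 9 of 16 immune receptors (13 adjusted over the list alone, camera adjusted p = 9.6e-06, adjusted p = 0.33 with an estimated correlation). Endoplasmic reticulum genes were higher in 9 of 17 (13 adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.33 with an estimated correlation). Heat shock genes were lower in 5 of 12, HSP101 (−1.94 ± 0.19; 6 adjusted over the list alone, camera adjusted p = 8.9e-04, adjusted p = 0.30 with an estimated correlation).

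At 8 h PR1 was lower in npr1 (−6.69 ± 1.09), WRKY62 (−5.91 ± 0.49) and WRKY54 (−3.99 ± 0.34), while ICS1 was higher by 0.99 ± 0.25. VSP2 was higher by 3.27 ± 0.42, MYB75 by 2.74 ± 0.28, PDF1.2A by 1.51 ± 0.50 and CYP81F2, of indole glucosinolates, by 1.99 ± 0.28. Of 23 salicylic acid genes 14 were lower (17 adjusted over the list alone, camera adjusted p = 3.6e-09, adjusted p = 0.33 with an estimated correlation). Jasmonate and ethylene defence outputs were higher in 6 of 11 (7 adjusted over the list alone, camera adjusted p = 0.020, adjusted p = 0.53 with an estimated correlation) and anthocyanin genes in 7 of 15 (7 adjusted over the list alone, camera adjusted p = 1.4e-05, adjusted p = 0.30 with an estimated correlation).

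At 12 h PR1 was lower in npr1 (−4.35 ± 1.09), WRKY62 (−6.89 ± 0.49) and WRKY66 (−7.04 ± 0.58), and ICS1 was higher by 1.14 ± 0.25. CHS was higher by 2.88 ± 0.40, and JAZ8 and AOC1 were lower (−1.86 ± 0.33 and −1.64 ± 0.24). Anthocyanin genes were higher in 12 of 15 (13 adjusted over the list alone, camera adjusted p = 5.3e-11, adjusted p = 0.18 with an estimated correlation). Jasmonate synthesis and JAZ genes were lower in 11 of 22 (12 adjusted over the list alone, camera adjusted p = 3.7e-06, adjusted p = 0.39 with an estimated correlation), and salicylic acid genes lower in 9 of 23 (12 adjusted over the list alone, camera adjusted p = 1.8e-04, adjusted p = 0.53 with an estimated correlation). Vascular markers were lower in 3 of 9 (8 adjusted over the list alone, camera adjusted p = 0.0029, adjusted p = 0.30 with an estimated correlation) and guard cell markers higher in 3 of 6 (4 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.30 with an estimated correlation).

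The limma tests of npr1 against wild type called 294 genes at 0 h (110 higher, 184 lower), 3951 at 4 h (1804, 2147), 4755 at 8 h (2273, 2482) and 3999 at 12 h (2050, 1949). With the scan session as a block they called 550, 6046, 6705 and 5980. Normexp, session 2 alone and only the groups compared gave fewer than the main fit at every time, with counts given further below. Leaving out wild type 0 h replicate 2, the count at 0 h was 599, and without replicate 3 it was 98. At 4 h it was 2196 without wild type 4 h replicate 2, and the authors' processed values gave 605 higher and 1418 lower. With normexp the calls of NIMIN2, ICS2, COR47, ERD10, PAD3, UGT74F1 and WRKY38 at 0 h and of PDF1.2A at 8 h ended. Session 2 lost the same 8 calls, those of ICS1, PAD4 and EDS1 at 4 h, of ICS1 at 8 h, and of ICS1, JAZ8 and PR1 at 12 h. Fold changes of the 2 sessions correlated across all tested genes at r = 0.66, 0.79, 0.86 and 0.87.

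**Figure D4:**
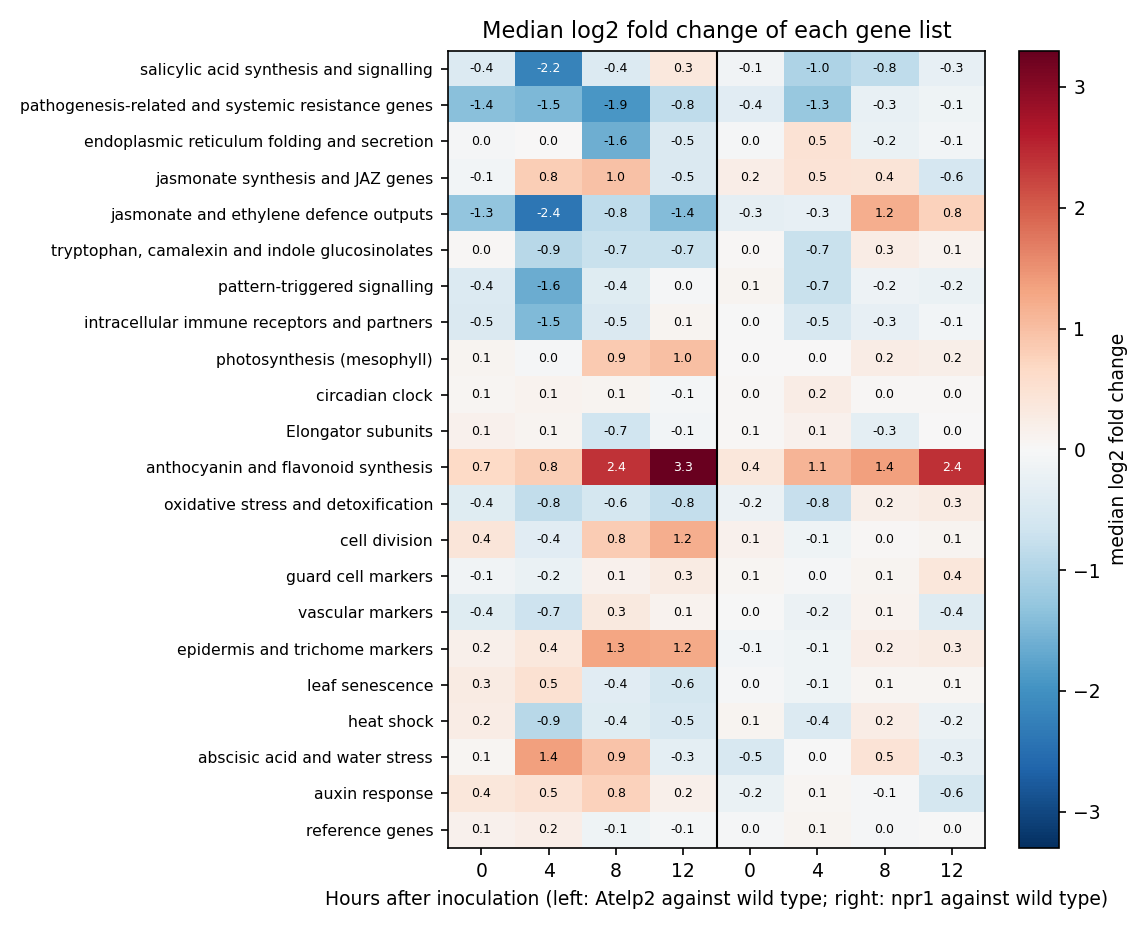
Median log2 fold change of the tested genes of each of 22 lists (colour and number), for Atelp2 (left) and npr1 (right) against wild type at each time point, from 3 arrays per group. The anthocyanin list reached 3.27 in Atelp2 and 2.42 in npr1 at 12 h.

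The change from 0 h itself differed between Atelp2 and wild type in 5121, 10141 and 5292 genes at 4, 8 and 12 h. Values here are the signed change in the mutant minus that in wild type, and higher and lower refer to this difference. At 4 h it was −4.61 ± 0.35 for ICS1 and −6.54 ± 0.85 for PAD3, 5.76 ± 0.32 for JAZ7 and 10.16 ± 0.54 for PHI-1. At 8 h it was 5.24 ± 0.59 for VSP2, and −1.81 ± 0.20, −1.91 ± 0.16 and −1.15 ± 0.15 for BIP2, PDIL1-2 and ELP2. At 12 h it was 2.24 ± 0.46 for WRKY70, 2.15 ± 0.35 for CBP60G, 3.39 ± 0.58 for LHCB1.1 and −4.42 ± 0.42 for GH3.3. Salicylic acid genes were lower in 14 of 23 at 4 h (18 adjusted over the list alone, camera adjusted p = 7.1e-07, adjusted p = 0.44 with an estimated correlation) and higher in 11 at 12 h (12 adjusted over the list alone, camera adjusted p = 2.8e-05, adjusted p = 0.52 with an estimated correlation). The endoplasmic reticulum list was lower in 15 of 17 at 8 h (15 adjusted over the list alone, camera adjusted p = 1.5e-09, adjusted p = 0.19 with an estimated correlation). The same held for all 6 Elongator subunit genes (6 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.31 with an estimated correlation).

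Between npr1 and wild type the change differed in 722, 2276 and 1383 genes. The same signed difference at 4 h was −2.93 ± 0.48 for WRKY54, −1.48 ± 0.35 for ICS1 and 1.33 ± 0.21 for ERD10. At 8 h it was −3.25 ± 0.48 for WRKY54, and 2.67 ± 0.59, 2.54 ± 0.40 and 3.73 ± 1.1 for VSP2, MYB75 and PR2. At 12 h it was −2.53 ± 0.47 and −2.90 ± 0.47 for WRKY53 and JAZ8, and 4.48 ± 0.96 and 1.94 ± 0.29 for the flavonoid genes UF3GT and F3H. The salicylic acid list was lower in 12 of 23 at 8 h (15 adjusted over the list alone, camera adjusted p = 2.1e-06, adjusted p = 0.45 with an estimated correlation). The anthocyanin list was higher in 6 of 15 at 12 h (11 adjusted over the list alone, camera adjusted p = 8.7e-09, adjusted p = 0.19 with an estimated correlation).

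In the limma tests of these differences, the higher and lower counts were 2497 and 2624, 5022 and 5119, and 2914 and 2378 for Atelp2, and 236 and 486, 1084 and 1192, and 718 and 665 for npr1. With the scan session as a block the counts were 6971, 12257 and 7753 for Atelp2 and 1665, 3813 and 2611 for npr1. With normexp npr1 at 4 h gave 11 higher and 13 lower, and without wild type 4 h replicate 2 its count was 300. The ICS1 call for npr1 at 4 h ended with normexp and with the authors' values, the ERD10 call at 4 h with the authors' values, the JAZ8 and UF3GT calls at 12 h with normexp, and the PR2 call at 8 h when wild type 0 h replicate 3 was left out. In session 2 the calls of WRKY54, ICS1 and ERD10 at 4 h, VSP2, MYB75 and PR2 at 8 h, and WRKY53, JAZ8, UF3GT and F3H at 12 h ended for npr1. Normexp moved the median of all genes to 0.23 and 0.21 for Atelp2 at 8 and 12 h.

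Set against each other, the mutants differed in defence and secretory genes. At 0 h CML41 was higher in Atelp2 than in npr1 by 5.80 ± 0.40, and PHI-1, RPS2 and JAZ7 were lower (−4.75 ± 0.38, −1.48 ± 0.21 and −2.35 ± 0.22). At 4 h ICS1 was lower (−3.12 ± 0.25) and MKK4 (−2.58 ± 0.17), and PDF1.2A was at least 49.5-fold lower (adjusted p = 3.0e-10). At 8 h WRKY62 and WRKY54 were higher in Atelp2 by 5.99 ± 0.49 and 3.13 ± 0.34, and BIP2, ORA59 and PR2 lower (−1.62 ± 0.14, −3.67 ± 0.37 and −3.34 ± 0.78). At 12 h WRKY62, WRKY66 and NIMIN1 were higher by 8.35 ± 0.49, 6.43 ± 0.58 and 3.71 ± 0.52, and the glutathione transferase genes GSTU1 and GSTU25 lower (−3.14 ± 0.24 and −5.04 ± 0.37). The salicylic acid list was lower in Atelp2 in 14 of 23 at 4 h (16 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.52 with an estimated correlation) and higher in 14 at 12 h (19 adjusted over the list alone, camera adjusted p = 6.5e-05, adjusted p = 0.50 with an estimated correlation). Jasmonate and ethylene defence outputs were lower in 8 of 11 at 4 h (10 adjusted over the list alone, camera adjusted p = 2.1e-04, adjusted p = 0.35 with an estimated correlation). Lower at 8 h was the endoplasmic reticulum list, in 16 of 17 genes (16 adjusted over the list alone, camera adjusted p = 2.5e-10, adjusted p = 0.21 with an estimated correlation).

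The limma tests between the mutants called 4073, 7697, 11501 and 7629 genes at 0, 4, 8 and 12 h, 2328, 3839, 6098 and 4388 of them higher in Atelp2. With the scan session as a block they called 6167, 9951, 13628 and 9856. The authors' processed values split them as 3327 higher and 2130 lower at 4 h, 3487 and 5970 at 8 h, and 2086 and 2979 at 12 h.

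Genes that differed from wild type in both mutants went mostly the same way. At 4 h 1250 genes were higher in both and 1806 lower in both, where independent calls would share 446 and 455, and 103 went in opposite directions (913 if independent). At 8 h the counts were 1601, 1655 and 363, at 12 h 1127, 678 and 407, and at 0 h 73, 124 and 18. ICS1, PAD4 and EDS1 were among those lower in both at 4 h, and PR1 among those lower in both at 8 and 12 h. Both comparisons use the same 3 wild-type arrays, and simulations in which those arrays alone were shared gave a median correlation of r = 0.57, 0.53, 0.55 and 0.40 at 0, 4, 8 and 12 h. The measured correlation was r = 0.41, 0.66, 0.54 and 0.38, above that median at 4 h only. The simulated arrays held no genotype effect, which the measured ones do, so these values of r are not alike and do not decide on sharing. The covariance of the 2 sets of fold changes was 0.333, 0.324 and 0.170 at 4, 8 and 12 h, against 0.132, 0.179 and 0.144 in the highest of 25 draws. At 0 h the covariance of 0.0819 lay below the highest draw, 0.142. After the results were seen, the wild-type arrays were divided 1 against 2, so that the mutants shared none of them. The covariance was then 0.0368 (0.00620 to 0.0580) at 0 h, 0.309 (0.240 to 0.336) at 4 h, 0.287 (0.255 to 0.299) at 8 h and 0.111 (0.0450 to 0.209) at 12 h, as median and range of 6 divisions. The median r of these divisions was 0.14, 0.57, 0.43 and 0.23. Calls were not counted with divided controls, so the part of the shared calls that comes from the shared controls was not separated. At 4 h the mutants shared slides and wild type lay on others, which dividing the controls leaves in place. The overlap at that time cannot be told apart from a difference between slides.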

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

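The tests of the Atelp2 response against wild type's were chosen after the results were seen. The neighbour tests and the splits of the samples were chosen before. The iron shortage test was written down before it was run, but a result of these data, the higher iron regulators, prompted it.

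The change from 0 h differed between genotypes in a direct test of the difference, which is what marked these counts out: 5121, 10141 and 5292 genes for Atelp2 and 722, 2276 and 1383 for npr1 at 4, 8 and 12 h. Splits of the samples were fitted without a block, over the 21193 genes with a value on every array. There the real counts were 5094, 10096 and 5268 for Atelp2 and 720, 2259 and 1376 for npr1. Of 100 splits, the real one included, 6, 2 and 3 gave as many for Atelp2, where the highest others were 7401, 11265 and 5999. The share was under 0.05 at 8 and 12 h, and not at 4 h. For npr1 10, 6 and 10 splits gave as many, with the highest others at 3005, 2913 and 2817, so that the share was not under 0.05 there. In each comparison the other splits that reached the real count left the real groups of one time whole. They thus measure the genotype difference at that time, a structure of the samples that the splits keep. The shares therefore cannot decide whether chance gave the counts, in either mutant. With both times mixed, the highest counts were 13, 1 and 5 for Atelp2 and 38, 1 and 1 for npr1. Such splits put real group differences into the residual spread, which lowers their counts. These low counts therefore do not decide on chance either.

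Comparisons of 3 arrays with 3 allow 10 splits, too few for a share under 0.05. In each, 1 of the 10, the real split, gave as many genes. The other splits mix arrays of 2 real groups, so real differences enter their residual spread and lower their counts. The gap to the real count is thus no test of chance. Real and highest other counts follow, over the genes with a value on every array. Wild type at 4, 8 and 12 h against 0 h gave 12913 and 0, 16658 and 1, and 16273 and 0. Atelp2 gave 12760 and 94, 14599 and 2, and 15432 and 0, and npr1 12204 and 1, 16359 and 0, and 16346 and 0. Against wild type at 0, 4, 8 and 12 h, Atelp2 gave 5251 and 101, 9741 and 0, 12806 and 1, and 7966 and 610, and npr1 290 and 84, 3935 and 0, 4726 and 1, and 3990 and 3. Atelp2 against npr1 gave 4056 and 3, 7667 and 1, 11446 and 0, and 7586 and 38.

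Probes that name no locus carried signal outside the tests of genes: of 2907 kept, 1535 changed in wild type from 0 to 8 h, 609 of them upward.

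The change from 0 h in Atelp2 followed that in wild type with a slope under 1, which need not mean a smaller change. At 4 and 8 h these genotypes lay on different slides, so a difference between slides cannot be told apart from genotype there. At 0 and 12 h they shared slides. Over genes called in the npr1 course, the slope of the change in Atelp2 on that in wild type was 0.70 at 4 h, 0.69 at 8 h and 0.81 at 12 h (95% intervals 0.57 to 0.83, 0.64 to 0.72 and 0.72 to 0.89). Each interval comes from 500 draws of the 3 arrays of each group with replacement. So few arrays can make it too narrow. The choice among the scalings run is argued against, since the highest slope at 8 h under the others was 0.71. Each of them sets the arrays to a common level, so an error from that step itself stays open. A slope also falls under 1 where the 2 changes differ from gene to gene or wild type's values are noisy. Genes called at 2-fold or more numbered 2653 higher and 3050 lower in Atelp2 at 4 h, against 2927 and 2774 in wild type. At 8 h they were 3377 and 4350 against 4793 and 6301, and at 12 h 3898 and 5191 against 4533 and 5952. By the slopes, a smaller response at every time stays open, but these counts do not show one at 4 h. A delay cannot be told apart from a smaller response, because the slope at 12 h, 0.81, is nearer 1 but still below it. The slope does not describe every gene. Mean log2 signal of EDS1 was lower in Atelp2 than in wild type at 4 h (0.50 against 3.49) and higher at 12 h (2.98 against 1.92). PAD4 did the same (2.43 against 6.10, then 5.84 against 4.85). PR1 and PR5 had lower means in Atelp2 at 12 h (1.18 against 4.30 and 3.13 against 3.95). A lower dose or later inoculation of the Atelp2 plants cannot be told apart either, as no bacterial count was used here. The slope of npr1, over genes called in the Atelp2 course, was 0.87 at 4 h (0.77 to 0.94), 0.94 at 8 h (0.88 to 0.99) and 0.95 at 12 h (0.87 to 1.02). At 4 and 12 h these intervals overlap those of Atelp2, though the slopes of the 2 mutants rest on different genes. The npr1 plants share no dose record with the Atelp2 plants.

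Genes that differed from wild type in the same direction at all 4 times numbered 834 in Atelp2 and 65 in npr1. DNA near the mutated gene, or another linked stretch that differs from wild type, could set such genes apart, and they lay near one another more often than random genes. Within 10 tested genes there were 357 pairs in Atelp2 (random median 325, one-sided permutation p = 0.038) and 8 in npr1 (random median 2, permutation p = 0.0014). Near the target itself the excess was small or absent, with 11 genes within 100 of ELP2 against 7.86 expected, and 0 near NPR1 against 0.615. Related genes in tandem arrays also lie side by side, and a biological effect of each mutation stays open and was not tested apart.

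The iron regulators BHLH100, bHLH38, bHLH39 and BHLH101 were higher in Atelp2 at all 4 times, by 6.58 ± 0.79, 4.77 ± 0.64, 5.57 ± 0.53 and 4.69 ± 0.43 at 0 h, where wild type had BHLH100 and bHLH39 above background on 2 of 3 arrays. A wider iron shortage response is in line with the other genes tested: 9 of 10 further genes known to rise under iron shortage were higher at 0 h and 3 of 3 ferritin genes lower. Later, at 4, 8 and 12 h, 8, 7 and 7 of the 10 were higher in Atelp2, and 1 was lower at 4 h. Ferritin genes were lower in 3, 3 and 2 of 3. The regulators had prompted the iron shortage test. AT1G47400 and AT2G30766 among the 10 were also among the genes furthest from wild type at all 4 times. The test is thus not independent of the pattern. Whether the plants differed in iron content or in soil was not measured, so growth conditions stay open beside the mutation.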

How the results depend on the processing

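Session 2 alone and the session block for gene lists were chosen after the data were seen. Every named value kept its sign under the alternatives run except NPR1 in Atelp2 at 12 h, which was not called, turned to −0.087 with the authors' processed values, and ran from −0.021 (without Atelp2 12 h replicate 3) to 0.106 leave-one-out. Of 193 named values, 38 lost their call under at least 1 alternative: 14 with normexp, 10 with the authors' values, 13 with only the groups compared, 34 in session 2 and 2 with quantile normalization (COR47 and ERD10 in npr1 at 0 h), which also called PAD4 in Atelp2 at 8 h. Over the 1296 pairs of a value and a left-out array, 34 lost a call, 2 became called and 1 changed sign. Against wild type the lost ones were COR47, ERD10, NIMIN2 and WRKY38 in npr1 at 0 h, PAD4 at 4 h and PDF1.2A at 8 h, and in Atelp2 PR2 at 0 h and PR1 at 12 h. For the change in npr1 they were ICS1 at 4 h and PR2 at 8 h. With only the groups compared, npr1 lost COR47, ERD10, ICS2, MRD1, NIMIN2, PAD3 and UGT74F1 at 0 h and PDF1.2A at 8 h. Atelp2 lost PR2 at 0 h, PR1 at 4 h and, in its own course, ICS1 at 4 h, and the change in npr1 lost PR2 at 8 h and WRKY53 at 12 h. Beyond the calls named with the results, normexp and session 2 ended BHLH100 in npr1 at 4 h, and the authors' values COR47, ERD10 and NIMIN2 at 0 h and PAD4 and PDIL2-2 at 4 h in npr1. No named value lost its call without the filter, with the mean of all probes, or with a replicate, session or slide block. Depth limits the dim genes, since 66.0% to 75.7% of spots were well above background, and a bound stands in for their fold.

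Counts of genes stayed within 1.5 times under quantile normalization, without the filter and with the mean of all probes, in all 27 comparisons. Elsewhere these moved further, and the cause was not tested, except that session 2 and only the groups compared have fewer arrays or degrees of freedom. With normexp background correction the counts were, for Atelp2 against wild type 2536, 5860 and 3886 at 0, 4 and 12 h, npr1 against wild type 29, 1184, 1895 and 1248 at 0, 4, 8 and 12 h, the change in Atelp2 2318, 6115 and 2165 at 4, 8 and 12 h, the change in npr1 24, 533 and 257 at 4, 8 and 12 h, and Atelp2 against npr1 1454, 3919, 7415 and 3948 at 0, 4, 8 and 12 h. The authors' processed values gave Atelp2 against wild type 3074 and 5113 at 0 and 12 h, npr1 against wild type 138, 2023, 2639 and 2105 at 0, 4, 8 and 12 h, the change in Atelp2 2480 at 12 h, the change in npr1 247, 1087 and 606 at 4, 8 and 12 h, and Atelp2 against npr1 2167 and 5065 at 0 and 12 h. With only the groups compared they were Atelp2 against wild type 4797 at 12 h, npr1 against wild type 33, 1758, 2818 and 1779 at 0, 4, 8 and 12 h, the change in npr1 223 and 790 at 4 and 12 h, and Atelp2 against npr1 3995 and 4731 at 4 and 12 h. In scan session 2 alone they were Atelp2 against wild type 3434 at 0 h, npr1 against wild type 33, 612, 2696 and 1766 at 0, 4, 8 and 12 h, the change in Atelp2 2977 and 2138 at 4 and 12 h, the change in npr1 1, 593 and 213 at 4, 8 and 12 h, and Atelp2 against npr1 2584 and 4931 at 0 and 12 h. For the change in npr1 at 4 h in session 2 the gene was WRKY59 (−4.76, adjusted p = 0.0065), and 1816 genes had an unadjusted p under 0.05 in limma. The scan session as a block gave npr1 against wild type 550 and 6046 at 0 and 4 h, the change in npr1 1665, 3813 and 2611 at 4, 8 and 12 h, and Atelp2 against npr1 6167 at 0 h. With the slide as a block came Atelp2 against wild type 8114 at 0 h, npr1 against wild type 677, 7434 and 6628 at 0, 8 and 12 h, the change in Atelp2 8159 at 12 h, the change in npr1 1169, 4239 and 3115 at 4, 8 and 12 h, and Atelp2 against npr1 6858 at 0 h. Leaving out 1 array in turn, npr1 against wild type gave 98 to 599 genes at 0 h and 2196 to 3731 at 4 h, and the change in npr1 300 to 955 at 4 h. A group left with fewer arrays is assumed to vary like the others.

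Same-numbered arrays deviated together in 180 of 198 pairs at r over 0.1 (median 0.39, lowest −0.22), and 152 correlated best with their own number, a hint of pairing from the data. As the labels name no shared batch or day and not every pair passed 0.1, the number is taken as shared and not as a pairing. Still, each slide held arrays of the same number. In npr1 against wild type all 3 pairs passed 0.1 at 4, 8 and 12 h, and 2 of 3 at 0 h. The fits without a block may thus leave out a real pairing. A replicate block gave npr1 against wild type 611, 6258 and 6187 at 0, 4 and 12 h, the change in Atelp2 7986 at 12 h, the change in npr1 1862, 4011 and 2805 at 4, 8 and 12 h, and Atelp2 against npr1 6361 at 0 h. Genes called in the same direction in both mutants then numbered 403, 4618 and 2957 at 0, 4 and 12 h. The replicate block moved no other count over 1.5 times.

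With an estimated correlation camera called 0 gene lists in each family, against 135, 66, 44 and 38 in the courses, the genotype comparisons, the differences of change and the mutant comparisons. At an unadjusted p under 0.05 it gave 45, 24, 19 and 9. With a replicate block 133, 60, 40 and 35 of them stayed called, with a session block 133, 61, 40 and 34, and in session 2 131, 56, 40 and 31.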

Other observations

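A small set of genes differed from wild type in both mutants at every time. Of 25 such genes, 24 went the same way in both, 17 higher and 7 lower. MRD1 was 2.88 and 4.41 higher at 0 h in Atelp2 and npr1, and EXPA10, an expansin gene, 1.57 and 1.04. HO3, a heme oxygenase gene, stood at −1.55 and −1.33, and IAR3 and ILL5 at −2.21 and −2.0 and at −2.1 and −1.84. Between the mutants 5, 9, 15 and 10 of the 24 differed at 0, 4, 8 and 12 h. These genes were singled out after their values were seen, and both comparisons share the wild-type arrays.

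In npr1 iron regulators were also higher than in wild type at 4 h. BHLH100, dim on all 3 wild-type arrays, was at least 2.58-fold higher (limma adjusted p = 0.0017), and bHLH38 was higher by 2.59 ± 0.64 and BHLH101 by 1.40 ± 0.43, above background on 2 and 1 of 3 wild-type arrays. The BHLH100 call ended with normexp and in session 2. bHLH39 was dim on all 3 wild-type arrays and called higher too (adjusted p = 0.0042), for which no bound was computed. At 12 h BHLH101 was higher by 1.27 ± 0.43, above background on 2 of 3 wild-type arrays, and bHLH39, dim on all 3 of them, was called higher (adjusted p = 5.5e-04). At 0 h the adjusted p ran from 0.65 upward over the 4 genes, and at 8 h from 0.34. Of the 10 further genes known to rise under iron shortage, 1, 4, 3 and 1 were higher in npr1 at 0, 4, 8 and 12 h. At 4 h 1 of the 10 was lower. Of the 3 ferritin genes, 1, 1, 2 and 0 were lower at these times.

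Scan session 1 held brighter arrays, with a 75th percentile of signal from 3480 to 6829 against 1622 to 4345 in session 2. Negative control spots read 28.5 to 49.3 and 52.8 to 71.5. PR1 varied between replicates, at −4.17, −7.45 and −2.38 (log2 minus the 75th percentile) in wild type at 0 h and −1.98, 0.46 and −5.90 in Atelp2 at 4 h.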
